A study of Homo sapiens with 12 samples.

How the data were processed

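Poly(A)-selected RNA of 12 libraries was sequenced, per the labels' protocols, from the choriocarcinoma lines JAR, JEG-3 and BeWo, 36 h after transfection of 150 nM inhibitor with a cationic lipid. Groups were taken from the sample labels. CK-3 and IN-3 in the titles are the control and the inhibitor of the miR-371a-5p set, and CK-5 and IN-5 those of the miR-518a-3p set, and the labels name a control inhibitor for both control groups. The series concerns genes regulated by these 2 microRNAs in the 3 lines. Each group holds 1 library per line.

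The deposited table holds, for 50868 genes and every library, a raw read count and an FPKM value, per the file headers, together with gene identifiers, symbols and positions. Reads were aligned with HISAT2 2.0.4 to hg38, and edgeR and DESeq2 (versions not given) were used, per the submitters' processing notes. The counting tool, the annotation and the use of strand are not given in the sources used here. The deposited FPKM were checked against the counts in 9316 genes, where the ratio of count to FPKM followed the column totals with a largest relative deviation of 1.48e-05, so both describe the same reads. Of the gene identifiers, 50111 were found in GENCODE 29, 99.8% of them at overlapping positions and 94.7% with the same start and end, and positions are printed as the table gives them (GRCh38). No column of the table was left without a sample. In all 12 libraries 17779 genes were at 0.

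The design fixed before the data were examined assumed FPKM and limma, with the provision that edgeR on counts takes its place where the table holds raw counts. Since it does, the main test is edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the counts as deposited with TMM scaling, on the 11540 genes with a mean FPKM of at least 1, which hold 98.1% of all counts, and a call is a Benjamini-Hochberg adjusted p under 0.05. TMM factors ranged from 0.830 to 1.14. Inhibitor contrasts were fitted with the 6 pairs of line and set as blocks, all 12 libraries in 1 fit (residual degrees of freedom 4, common biological coefficient of variation 17.4%), and the contrast is the mean over the 3 lines. Control sets and lines were compared in a fit with line and group (residual degrees of freedom 6, coefficient of variation 18.0%). The pairing comes from the same cell line in the labels. In the pairing check, the deviations of the libraries of a pair from the mean of their line and the mean shift of their group correlated with r between -0.37 and -0.14 across genes. These deviations sum to 0 over the 4 libraries of a line, which by itself makes such correlations negative. The check therefore does not show that libraries of a pair were closer to each other than to the rest of their line. Fold changes per line come from 1 library per arm and have no replicate check. CPM are scaled by TMM.

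Lists of genes for placental functions, signalling, stress, metabolism, RNA quality and other cell types, 29 in all, were fixed before the data were examined, and 25 had at least 3 measured members. They were tested with camera at the preset correlation of 0.01, again with an estimated correlation, and with fry. Seed sites of the mature microRNAs were searched in the longest annotated 3' UTR of 9388 tested genes (GENCODE 29, median length 1236.5 bases, Python 3.11.15), and each difference was set against 100 other 7-mers. The genes named were chosen by a rule fixed in advance. Per inhibitor these are the called genes with the same sign in 3 lines, filled up with the genes of largest shared FPKM ratio (up to 10 per direction, given as values only). Per pair of lines they are the 8 largest called changes in each direction, for differences between inhibitors and between control sets the 5 smallest p, for each described list up to 4 members with the largest statistic, and always CGA, GCM1, ERVW-1, ERVFRD-1, HLA-G, TFAP2C, GATA3, MKI67 and CDKN1A. Clone names, XIST and Y-linked genes were left out, and genes named outside the rule are said to be. The genes of the microRNAs themselves had no entry in the table, so the inhibitors' action on them was not analysed here.

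The total count per library ranged from 12126364 to 19948686. Where a group had no count, a fold is a lower bound from a floor of 3 counts over the libraries of the group, and with 1 to 3 counts the text gives the counts of both groups or the ratio with its exact counting interval. Reads carry no molecular identifiers, so intervals and floors cover counting error only. The procedure was tested on simulated counts drawn for the 11540 genes from the real means and library sizes. Changed genes were taken only from those with a mean count of at least 50 and no library at 0. For the inhibitor and control-set contrasts they got the same fold in all 3 lines. For the line comparison JEG-3 was first given the means of BeWo. The recovered shares therefore do not cover weakly expressed genes or changes that differ in size between lines. In 5 runs with 50 genes changed per fold size, the inhibitor contrast recovered 16.0% at 1.5-fold, 68.0% at 2-fold, 96.8% at 4-fold and 98.8% at 8-fold, with a mean of 11.2 false calls, the comparison of control sets 23.6%, 74.8%, 98.8% and 100% with 6.6, and the line comparison 33.6%, 84.8%, 98.4% and 100% with 6.8. A changed list of 18 genes was called in 5 of 5 runs and 0 of 120 unchanged lists were, with camera at the preset correlation. The simulated genes were drawn independently, so these runs cannot show false list calls that come from correlated genes. In the data the estimated correlation of the interferon list was 0.47 with the miR-518a-3p inhibitor. With the observed fold changes shuffled over genes, the seed difference had an SD of 0.0107 for the 216 genes with a miR-518a-3p site. Shuffling treats genes as independent.

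Alternatives fixed in advance were DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), quantile and median-ratio scaling, no filter and a filter at a mean FPKM of 5, other blocks, only the libraries of 1 inhibitor or of 2 lines, leaving out each line or library, an estimated correlation for lists, other site definitions and other sizes of fold. Comparisons with the control libraries of the other set, with both sets together, and without the controls of the miR-518a-3p set were added after seeing the data.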

Results

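RNA was sequenced from 12 poly(A)-selected libraries of JAR, JEG-3 and BeWo, 3 human cell lines derived from choriocarcinoma, a malignant tumour of placental trophoblast. Each line had been transfected with an inhibitor of miR-371a-5p, an inhibitor of miR-518a-3p, or the control inhibitor of either set, at 150 nM, and was collected after 36 h. Each of the 4 groups therefore held 3 libraries, 1 per line, and each line held 4 libraries, 1 per group. The total count per library ranged from 12126364 to 19948686, and 11540 of the 50868 genes in the table passed the expression filter. Libraries of the same line were close to each other, with Pearson's r of log2 values across genes between 0.977 and 0.988 in 18 pairs, against 0.692 to 0.831 in 48 pairs of different lines. No pair of libraries was closer than sampling noise, since the chi-square statistic per gene was 3.19 to 20.5 within lines. With 1 library per line and group, the p-values measure how far group effects differ between the 3 lines. The same spread is how far line differences vary over the 4 groups. It cannot be split into a biological and a technical part, and nothing in the labels says how the cultures were separated. Levels are given as CPM (counts scaled by library size), with the SD over libraries, and fold changes as log2 values with their SE.

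To ask which transcripts depend on miR-371a-5p, a microRNA known from embryonic stem cells and germ cell tumours, each inhibitor library was set against the control library of the same line and set. PEG10, a retrotransposon-derived imprinted gene needed for placenta formation, stood at 34.4 CPM with the inhibitor and 9.40 without it in JAR, at 153 and 5.46 in JEG-3, and at 20.7 and 4.58 in BeWo. Its log2 fold change of 2.91 (SE 1.18) over 3 pairs did not pass the test, and in JEG-3 the control and inhibitor of the other set stood at 61.9 and 65.1 CPM. TRIM52, a tripartite motif protein, had a value of 1.67 (SE 0.37) and TSN, the RNA-binding protein translin, one of 1.64 (SE 0.57), with the same sign in all 3 lines. STBD1, VPS26A, a retromer subunit, and ZNF524 had values of 0.92, 0.78 and 0.62. On the lower side, CCDC69 had a value of -2.01 (SE 0.48), the recycling-endosome GTPase RAB11A one of -0.92 (SE 0.19), the early-endosome GTPase RAB5C one of -0.84. The mitochondrial import chaperone TIMM8B had a value of -0.85 (SE 0.17), CLDND1 one of -0.91 and RICTOR, the defining subunit of mTOR complex 2, one of -0.56. The remaining genes that the naming rule took were copies or noncoding loci whose reads can be shared with near-identical sequences, with values between -1.48 for TMSB4XP4 and 0.89 for PHKA1P1. Among them were RN7SKP292, SLC7A5P2, LYPLA2P1, CLEC4GP1 and RPPH1, the RNA of RNase P. SENP3-EIF4A1, a readthrough gene that overlaps both of its parents, had -1.63.

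Trophoblast genes had small values with this inhibitor, none of them called. CGA, the alpha subunit of chorionic gonadotropin, had a log2 fold change of -0.24 (SE 0.13), GCM1, the transcription factor of syncytium formation, one of -0.17 (SE 0.13). The fusogens ERVW-1 (syncytin-1) and ERVFRD-1 (syncytin-2) had values of -0.03 (SE 0.14) and 0.11 (SE 0.18), and HLA-G, the nonclassical HLA molecule of invasive trophoblast, one of 0.07 (SE 0.27). The lineage factors TFAP2C and GATA3 had values of 0.05 and 0.21, the proliferation marker MKI67 one of -0.40 (SE 0.54) and the p53 target CDKN1A one of -0.07 (SE 0.09). In BeWo MKI67 stood at 26.1 CPM with the inhibitor, in 1 library, against 85.9 to 89.6 in the other libraries of that line. None of the 11540 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.138, and 333 had an unadjusted p under 0.05. These were 2.89% of the genes, below the share of 0.05 that would be reached if no gene changed. DESeq2 called 4 genes (CCDC69, CTD-2132N18.3, RAB11A and TRIM52) and limma on log2(FPKM + 1) called 1 (CTD-2132N18.3). The uncharacterised, clone-named CTD-2132N18.3 was chosen after its values were seen. It had a log2 fold change of 1.56 (SE 0.15), with 1.69 in JAR, 1.40 in JEG-3 and 1.55 in BeWo, and of 0.84 (SE 0.14) with the other inhibitor.

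Among the 25 gene lists with at least 3 measured members, 4 stood apart with the miR-371a-5p inhibitor in camera at its preset correlation. The median log2 fold change was -0.08 for ribosomal proteins, with 66 of 79 lower, and -0.13 for nuclear-encoded respiratory chain subunits, with 21 of 23 lower. It was -0.37 for interferon-stimulated genes, with 17 of 18 lower, and 0.09 for cytotrophoblast genes, with 13 of 19 higher. Their Benjamini-Hochberg adjusted p in camera was 4.1e-04, 5.6e-04, 0.00432 and 0.0371 in that order, and adjusted p = 0.836 with an estimated correlation for each. No member of the 4 lists was called by edgeR's quasi-likelihood test over all genes or adjusted over the list alone. The interferon value came from JEG-3, where the median was -0.97, against -0.06 in JAR and 0.08 in BeWo.

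To ask the same of miR-518a-3p, a microRNA of the placenta-expressed cluster on chromosome 19, its inhibitor was set against the controls of its own set. PFKFB3 (ENSG00000170525; chromosome 10, 6144934 to 6235545, GRCh38), which makes the activator of the glycolytic enzyme phosphofructokinase, fell by 1.51 on the log2 scale (SE 0.09, 3 pairs), from 228 to 84.4 CPM in JAR, 43.2 to 14.2 in JEG-3 and 10.6 to 3.79 in BeWo. It was the 1 gene of 11540 that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at adjusted p = 0.00897, lower in 3 of 3 lines. CCL5 (ENSG00000271503; chromosome 17, 35871491 to 35880793), a chemokine induced by virus-sensing pathways, went from 10.1 to 1.17 CPM in JAR, 106 to 3.82 in JEG-3 and 5.56 to 0.228 in BeWo. Its log2 fold change was -4.30 (SE 0.39), with an adjusted p of 0.0556 in edgeR's quasi-likelihood test. The call of PFKFB3 was lost when any 1 line was left out, with an adjusted p of 0.139 without JAR, 0.150 without JEG-3 and 0.0669 without BeWo in edgeR's quasi-likelihood test. It was also lost with only the 6 libraries of the set (0.119), with line in place of the pair as block (0.816) and in limma on log2(FPKM + 1) (0.285). With a mean FPKM of at least 5 PFKFB3 was not among the genes tested, and the 1 gene called there was CCL5. Over all alternatives that tested it the adjusted p ranged from 4.1e-20 in DESeq2 to 1.0 without a block in edgeR's test. Against the control libraries of the other set its log2 fold change was -0.31 (SE 0.40), with 0.27 in JAR, 0.24 in JEG-3 and -1.57 in BeWo.

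The genes with the largest decreases shared by all 3 lines were mostly interferon-stimulated genes, and their values are given without a call. IFIT1 and IFIT3, which bind or sequester viral RNA, had log2 fold changes of -3.21 (SE 0.88) and -3.20 (SE 0.49), and the membrane antiviral proteins IFITM1 and IFITM3 -2.83 and -2.09. The helicases DDX60 and IFIH1 (MDA5, a sensor of double-stranded RNA) had -2.67 (SE 0.41) and -2.36 (SE 0.37), the ubiquitin-like modifier ISG15 -1.97 (SE 0.47), IFI6 -1.86 (SE 0.29) and the scramblase PLSCR1 -1.15 (SE 0.16). IFI6 went from 1266 to 412 CPM in JAR, 2143 to 412 in JEG-3 and 826 to 277 in BeWo. On the higher side SNX22, a sorting nexin, had 6.56 (SE 1.44), with 0.317 to 15.3 CPM in JAR, 0.588 to 54.5 in JEG-3 and 0.159 to 32.1 in BeWo. Its controls of the other set stood at 9.28 CPM in JAR, 0.613 in JEG-3 and 42.7 in BeWo. HMGCS1, the cytosolic enzyme that starts the mevalonate pathway, had 1.89 (SE 0.43), DLST, a subunit of the alpha-ketoglutarate dehydrogenase complex, 1.19 (SE 0.20), and ANKHD1 0.92 (SE 0.14). The protocadherin PCDHB2 had 1.78, ZBTB43 1.60, MAGEA8 1.05, the glycosyltransferase B3GNT3 0.75, C9orf78 0.41 and the pseudogene HIST1H1PS1, which can share reads with other histone H1 genes, 2.96. Trophoblast genes again had small values, 0.06 (SE 0.13) for CGA, 0.09 (SE 0.14) for GCM1, 0.35 (SE 0.15) for ERVW-1, -0.28 (SE 0.17) for ERVFRD-1, -0.19 (SE 0.27) for HLA-G, -0.04 for TFAP2C, 0.01 for GATA3 and -0.19 (SE 0.53) for MKI67. At an unadjusted p under 0.05 there were 531 genes, or 4.60%, below the share of 0.05 that would be reached if no gene changed. DESeq2 called 34 (7 higher and 27 lower, 11 of them members of the interferon list) and limma on log2(FPKM + 1) called 0.

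As a group, all 18 measured interferon-stimulated genes were lower with the miR-518a-3p inhibitor, with a median log2 fold change of -1.92. None of them passed over all genes in edgeR's quasi-likelihood test and all 18 passed adjusted over the list alone. In camera the Benjamini-Hochberg adjusted p was 3.2e-72 at the preset correlation, and adjusted p = 0.0691 with an estimated correlation. The summed level of the 18 genes was 2528 CPM in the JAR control and 625 with the inhibitor, 6827 and 2054 in JEG-3, and 1729 and 711 in BeWo, and the controls of the other set stood at 643, 3910 and 683 CPM in the same lines. Set against those other controls, the inhibitor libraries had a list median of -0.37.

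Of the other lists, 8 passed camera at the preset correlation and none of them with an estimated one. The 13 mitochondrially encoded mRNAs were all higher, with a median of 0.26 (Benjamini-Hochberg adjusted p in camera 5.6e-10, and adjusted p = 0.494 with an estimated correlation). The share of counts on all genes with a mitochondrial (MT-) symbol was 6.50% in the JAR control and 7.58% with the inhibitor. It was 5.49% and 6.64% in JEG-3, and 6.86% and 6.99% in BeWo, and the JAR inhibitor library was the shallowest of the 12. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, had a median of -0.25 with 11 of 12 lower, immediate early genes -0.19 with 12 of 15 lower, and YAP targets -0.25 with 9 of 11 lower. Their adjusted p in camera was 0.00395, 0.00395 and 0.00529, and adjusted p = 0.751, 0.494 and 0.494 with an estimated correlation. Against the controls of the other set the inhibitor libraries had medians of 0.14, 0.21 and -0.16 for these lists. Histone and immediate early genes thus went the other way there, and YAP targets the same way. Ribosomal proteins had a median of 0.05, respiratory chain subunits 0.06, hypoxia and glycolysis genes -0.05, PFKFB3 being their 1 called member, and genes of the unfolded protein and integrated stress responses -0.07. For these 4 lists camera gave adjusted p values of 0.00529, 0.0491, 0.00154 and 0.0491, and adjusted p = 0.836, 0.776, 0.766 and 0.766 with an estimated correlation. Set against the controls of the other set, their medians were 0.03, 0.05, 0.09 and 0.07. Hypoxia genes, with 19 of 22 higher, and stress response genes thus changed direction with the control set, and the others did not. Adjusted over the list alone, 1 gene each passed in the hypoxia, immediate early and stress response lists, all lower, and 0 in the other 5.

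**Figure D1:**
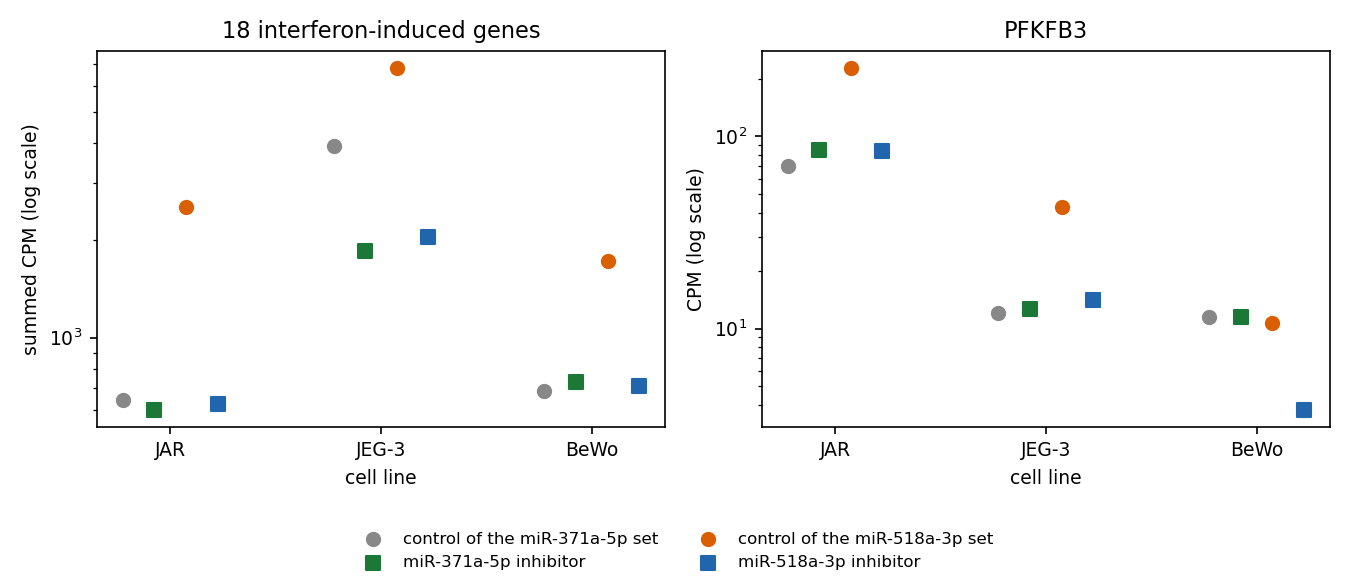
Summed CPM of the 18 interferon-stimulated genes (left) and CPM of PFKFB3 (right) in each of the 12 libraries, by cell line, on log scales, 1 point per library, with circles for controls and squares for inhibitors. The interferon sum was highest in the control of the miR-518a-3p set in each line, at 2528 CPM in JAR, 6827 in JEG-3 and 1729 in BeWo.

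Whether the responses to both inhibitors differed was tested directly. PFKFB3 had a difference (miR-518a-3p inhibitor minus miR-371a-5p inhibitor) of -1.64 (SE 0.13) on the log2 scale, at an adjusted p of 0.0501 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CCL5 had a difference of -3.76 (SE 0.57), and ZFP57, a zinc finger protein that maintains imprinting marks, one of -4.27 (SE 0.57). Its level in BeWo was 14.7 and 72.0 CPM in control and inhibitor of the miR-371a-5p set and 80.8 and 15.2 in those of the miR-518a-3p set. The lysosomal enzyme GUSB and the protocadherin FAT2 had -0.66 (SE 0.13) and -0.65 (SE 0.14). No gene passed, and 481 had an unadjusted p under 0.05, or 4.17%, below the share of 0.05 that would be reached if no gene changed. DESeq2 called 3 (CCL5, IFIT3 and PFKFB3), and limma on log2(FPKM + 1) called 0. By list, the median over genes of the difference was -1.44 for interferon-stimulated genes, 7 of them passing adjusted over the list alone, 0.32 for mitochondrially encoded mRNAs, 0.16 for respiratory chain subunits, 0.14 for ribosomal proteins and -0.13 for hypoxia and glycolysis genes. Benjamini-Hochberg adjusted p in camera was 5.5e-29, 2.8e-07, 5.8e-05, 2.0e-06 and 1.1e-04, and adjusted p = 0.347, 0.824, 0.824, 0.833 and 0.833 with an estimated correlation. Without JAR the interferon median was -0.96. Adjusted over the list alone, 1 hypoxia gene also passed, and none of the other 3 lists had a member that did. Per gene, the responses of different lines to one inhibitor were nearly unrelated across genes, with r between -0.09 and 0.07 for miR-371a-5p and between 0.02 and 0.09 for miR-518a-3p. Of all genes, 27.2% and 23.4% had the same sign in 3 lines, where independent signs give 25%.

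The controls of both sets had received a control inhibitor, and whether it was the same reagent or given on the same day is not stated. CCL5 rose by 3.70 on the log2 scale (SE 0.38) in the controls of the miR-518a-3p set over those of the miR-371a-5p set, from 1.42 to 10.1 CPM in JAR, 7.48 to 106 in JEG-3 and 0.139 to 5.56 in BeWo. It was the 1 gene called, at an adjusted p of 0.0425 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The call of CCL5 was lost when JEG-3 or BeWo was left out, with adjusted p values of 0.117 and 0.190 in edgeR's quasi-likelihood test, and 0.0208 without JAR. Over all 6 libraries 634 genes had an unadjusted p under 0.05, or 5.49%, close to the share of 0.05 that would be reached if no gene changed. IFNL1 and IFNL3, genes of the interferon lambda family, some of whose members can share reads, had values of 3.77 (SE 0.66) and 3.61 (SE 0.58) without a call. IFNL1 had 7 and 166 counts in the JAR controls, 48 and 372 in JEG-3 and 0 and 8 in BeWo. IFI6 had 1.57 (SE 0.25) and SERPING1, the complement C1 inhibitor, 0.79 (SE 0.12). All 18 interferon-stimulated genes were higher, with a median of 1.70, none passing over all genes and 17 adjusted over the list alone. Without JAR the median was 1.06. The list passed camera at the preset correlation (Benjamini-Hochberg adjusted p 4.6e-42) and with an estimated one (adjusted p = 0.0472 with an estimated correlation). Medians were 0.42 for histone genes, 0.32 for immediate early genes, 0.20 for hypoxia and glycolysis genes, 0.19 for TGF-beta and BMP targets and 0.16 for stress response genes. Camera gave adjusted p values of 1.4e-04, 4.3e-06, 3.2e-07, 0.0312 and 0.0119, and adjusted p = 0.431, 0.431, 0.431, 0.431 and 0.517 with an estimated correlation. Adjusted over the list alone, 1 gene each passed in the hypoxia and immediate early lists, both higher, and 0 in the other 3. DESeq2 called 26 genes here, 5 of them interferon list members, and limma on log2(FPKM + 1) called 2 (IFIH1 and IFIT3).

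As a count without a test, genes with a change of at least 2-fold, on the FPKM + 1 scale, in the same direction in all 3 lines were listed. There was 1 for the miR-371a-5p inhibitor (CTD-2132N18.3, higher), 9 for the miR-518a-3p inhibitor and 4 between the control sets. HMGCS1 was the 1 higher gene with the miR-518a-3p inhibitor, and CCL5, DDX60, IFI6, IFIH1, IFIT3, IFITM1, ISG15 and the clone-named CTD-2550O8.5, chosen after its values were seen, were the 8 lower ones. The 4 genes higher in the controls of the miR-518a-3p set were CCL5, DDX60, IFI6 and IFIT3. Both counts rest on the same control libraries of the miR-518a-3p set.

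A microRNA lowers transcripts that pair with its seed, so the genes with a seed site in the annotated 3' UTR were compared with genes without one. Genes without one also lacked the site less its first base (TTTGAG for miR-371a-5p, CGCTTT for miR-518a-3p). Genes holding only that shorter stretch were left out. For miR-371a-5p (site GTTTGAG) the median log2 fold change with its inhibitor was 0.015 higher in 1489 genes with a site than in 4961 without, which lay at the 43rd percentile of 100 other 7-mers found in similar numbers of genes. For miR-518a-3p (site GCGCTTT) it was 0.026 higher in 216 genes with a site than in 8422 without, above all 100 other 7-mers, which ranged from -0.037 to 0.021. By line this difference was 0.041 in JAR, 0.023 in JEG-3 and 0.041 in BeWo, at percentiles 90.0, 99.0 and 100. The same 216 genes lay at percentile 13 with the miR-371a-5p inhibitor. Neither set of site genes passed camera, where the Benjamini-Hochberg adjusted p over 8 tests was 0.524 for both, no gene with a miR-518a-3p site was called, and genes are not independent replicates.

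**Figure D2:**
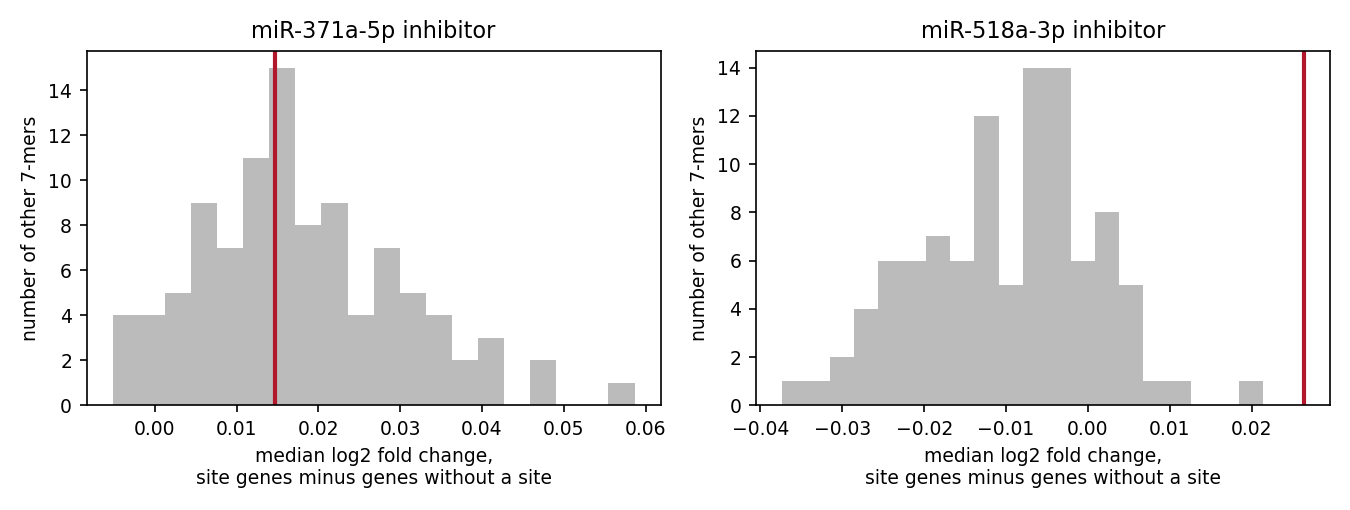
Histograms of the difference in median log2 fold change between genes with a 7-mer in the 3' UTR and genes that lack it even less its first base. Grey bars are 100 other 7-mers and the red line is the seed site of the inhibited microRNA, for the miR-371a-5p inhibitor (left) and the miR-518a-3p inhibitor (right). The line lies at the 43rd percentile on the left and above all 100 on the right.

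The 3 lines were then compared with each other, with 4 libraries per line. JEG-3 carried far more gonadotropin and HLA transcript than JAR, and its fusion genes went both ways. CGA (ENSG00000135346; chromosome 6, 87085498 to 87095406) stood at 26.9 ± 3.72 CPM in JAR and 996 ± 146 in JEG-3 (SD, n = 4), a log2 fold change of 5.20 (SE 0.14). CGB5, a chorionic gonadotropin beta gene whose reads can be shared with its near-identical copies, stood at 2.65 ± 0.634 and 177 ± 14.7 CPM. HLA-G (ENSG00000204632; chromosome 6, 29826967 to 29831125) rose from 0.221 ± 0.166 to 247 ± 21.5 CPM and HLA-C from 0.873 ± 0.251 to 440.5 ± 135. Of the fusion genes, ERVFRD-1 was higher in JEG-3, at 0.679 ± 0.222 in JAR and 71.7 ± 6.98 in JEG-3, and ERVW-1 (chromosome 7, 92468380 to 92477986) was lower, at 399 ± 44.9 and 39.9 ± 7.14, while GCM1 rose by 2.57 (SE 0.13). All of these passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at adjusted p values between 4.3e-09 for CGB5 and 1.3e-07 for GCM1. CDKN1A was higher by 1.07 (SE 0.09), GATA3 by 0.33 (SE 0.11), and TFAP2C and MKI67, which did not pass, had 0.23 (SE 0.10) and -0.34 (SE 0.48). In total 8678 of 11540 genes differed between JEG-3 and JAR, 4399 higher and 4279 lower in JEG-3, and 4481 of them by at least 2-fold (2174 higher, 2307 lower). With limma on log2(FPKM + 1), in which the median of all genes was 0.13, the split was 5039 higher and 3644 lower.

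Some genes were silent in 1 line. LGR6, a receptor of R-spondins, had no count in the 4 JAR libraries and was at least 1202-fold higher in JEG-3 (floor of 3 counts over the libraries of the group). Likewise at 0 in JAR and higher in JEG-3 were the host RNA SNHG18 at least 1130.1-fold, the ribosomal protein gene RPL39L at least 843-fold, the mesodermal transcription factor TWIST1 at least 708-fold, the insulin receptor substrate IRS2 at least 470.3-fold and IRX3 at least 349-fold. TACSTD2 (TROP2), a surface glycoprotein of trophoblast, had 3 counts in JAR and a ratio of 4527 (counting interval 1549 to 21956), and the retrotransposon-derived gene LDOC1 (chromosome X, 141175745 to 141177125) 1 count and a ratio of 5699 (counting interval 1023 to 225134). In the other direction IGFBP2, an insulin-like growth factor binding protein, fell from 198 ± 29.7 to 0.158 ± 0.0506 CPM, and PTGFRN by 9.39 on the log2 scale (SE 0.38). ADRA2C, the alpha-2C adrenergic receptor, had no count in JEG-3 and was at least 87.2-fold lower, and ZNF621, MTX3 and EXOC3L2 had 2 counts each there against 2279, 2320 and 1558 in JAR. TRPM2-AS, an antisense gene, and INO80B-WBP1, a readthrough gene, were at least 173-fold and 128-fold lower in JEG-3 and are uncertain, since the use of strand in counting is not stated. All 324 counts of INO80B-WBP1 in JAR came from 1 library, the control of the miR-518a-3p set, and its call was lost without that library.

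By list, 7 of 12 hormone genes were called higher and 3 lower in JEG-3, with a median of 0.80. Of 12 extravillous trophoblast genes 8 were higher and 2 lower, with a median of 2.04. Among the lower ones was MMP2, a matrix protease, at 909 ± 257 CPM in JAR and 17.3 ± 1.09 in JEG-3. Of 18 interferon-stimulated genes 16 were higher, with a median of 3.60, IFIT3 by 5.13 (SE 0.52), and their level also varied between groups within each line, as given above. Of 12 histone genes 10 were higher and 1 lower, with a median of 1.60, and of 20 stress response genes 13 were higher and 4 lower, with a median of 0.79. The chaperone HSPA5 (BiP) stood at 7304 ± 1944 CPM in JAR and 17111 ± 1275 in JEG-3, and ASNS, asparagine synthetase, rose by 2.49 (SE 0.12). Each of the 5 lists passed camera at the preset correlation, with Benjamini-Hochberg adjusted p values of 1.4e-04, 0.00984, 0.0101, 0.0106 and 0.0256, and adjusted p = 0.374, 0.615, 0.787, 0.615 and 0.615 with an estimated correlation. Adjusted over the list alone, the counts of members called were the same, except 4 in place of 3 lower hormone genes. Syncytium genes, with 9 higher and 5 lower of 17, did not pass camera at the preset correlation (adjusted p 0.50), nor did the 11 pluripotency and germ cell genes (adjusted p 0.268). Of the latter 8 were higher and 2 lower, among them the pluripotency RNA-binding protein LIN28A, which fell from 625 ± 65.7 to 78.6 ± 4.14 CPM.

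BeWo differed from JAR in single trophoblast genes, CGA, GCM1 and KRT7 among them. CGA stood at 1301 ± 80.0 CPM in BeWo (SD, n = 4), a log2 fold change of 5.59 (SE 0.14) over JAR. GCM1 (chromosome 6, 53126964 to 53148829) stood at 153 ± 8.20 against 9.62 ± 2.40 CPM, and the trophoblast keratin KRT7 at 507 ± 24.0 against 13.8 ± 0.543. ASCL2, an imprinted transcription factor of trophoblast, rose from 0.338 ± 0.0445 to 173 ± 14.8 CPM, the placental serine protease HTRA4 from 1.16 ± 0.357 to 599 ± 12, HLA-C from 0.873 ± 0.251 to 568 ± 59.0, and DHCR24, an enzyme of cholesterol synthesis, from 0.228 ± 0.133 to 152 ± 21.9. LIN28A fell from 625 ± 65.7 to 5.88 ± 1.51 CPM, the hypoxia-induced gene NDRG1 from 3095 ± 227 to 127 ± 10.1, and hexokinase HK2 from 1404 ± 138 to 86.7 ± 6.71. The immediate early genes JUN and PHLDA1 fell from 189 ± 103 and 216 ± 26.8 to 0.161 ± 0.131 and 0.934 ± 0.132. ERVW-1 fell by 1.15 on the log2 scale (SE 0.13) and ERVFRD-1 and HLA-G rose by 4.84 (SE 0.22) and 3.21 (SE 0.36). TFAP2C fell by 0.88 (SE 0.10), CDKN1A was -0.24 (SE 0.09), at an adjusted p of 0.0295 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, but positive in limma on log2 FPKM (0.10 at either pseudocount, 0.09 after quantile normalization). GATA3 and MKI67 did not pass, at 0.22 (SE 0.11) and -0.91 (SE 0.49). In total 9193 of 11540 genes differed, 4671 higher and 4522 lower in BeWo, and 5445 of them by at least 2-fold (2731 higher, 2714 lower). With limma on log2(FPKM + 1), in which the median of all genes was 0.28, the split was 5835 higher and 3517 lower.

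Silent genes again marked the lines. CDCP1 (chromosome 3, 45082278 to 45146422), a transmembrane glycoprotein, FAM114A1, SNHG18, the prostaglandin reductase PTGR1, ENPP5, the calcium channel TRPV4 and KDELC1 had no count in the 4 JAR libraries and were at least 1273-, 1236-, 663-, 639.9-, 481-, 427- and 424-fold higher in BeWo. The cancer-testis gene PASD1 had 1 count in JAR and a ratio of 5100.4 (counting interval 915 to 201481). The pseudogene USP32P1, which can share reads with its parent gene, ABHD3, the transcription factor SNAI2 and TMLHE, the first enzyme of carnitine synthesis, had no count in BeWo and were at least 892-, 884-, 469- and 345-fold lower. LRP2 (megalin), HOOK1 and ACSS3 had 2, 2 and 1 counts in BeWo against 6959, 3775 and 2718 in JAR, and GABRE, a GABA receptor subunit, fell by 11.09 on the log2 scale (SE 0.19).

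All 12 hormone genes were higher in BeWo than in JAR, with a median of 5.67, and this list passed camera at the preset correlation (Benjamini-Hochberg adjusted p 3.2e-12) and with an estimated one (adjusted p = 0.0400 with an estimated correlation). Extravillous genes had a median of 2.59 with 11 of 12 called higher, and syncytium genes 1.45 with 12 of 17 higher and 4 lower. Hypoxia and glycolysis genes had a median of -1.93 with 18 of 22 lower, immediate early genes -1.51 with 12 of 15 lower and 1 higher, and histone genes -2.16 with 11 of 12 lower. Cholesterol synthesis genes had a median of -0.92 with 17 of 23 lower and 6 higher, and ribosomal proteins -0.64 with 56 of 79 lower and 2 higher. RPL39L, at 0 in JAR, lies at the upper end of that list and its bound leaves the median in place. Camera gave adjusted p values of 1.4e-07, 0.0198, 9.1e-09, 4.1e-04, 4.8e-05, 0.0293 and 0.00160 at the preset correlation, and adjusted p = 0.252, 0.252, 0.252, 0.334, 0.252, 0.252 and 0.924 with an estimated correlation. Counts adjusted over the list alone were the same for these 8 lists. Of the markers of other cell types, those of immune cells had no member past the expression filter. The fibroblast collagens COL1A1 and COL5A1 stood at 13.4 and 5.39 CPM in JAR, 44.1 and 114 in JEG-3 and 25.5 and 8.29 in BeWo. In the same order, the endothelial genes ESAM and CDH5 stood at 3.53 and 6.69, 11.2 and 42.8, and 5.60 and 210.01, and the embryonic globin HBE1 at 11.5, 5.88 and 6.87. The embryonic globin HBZ had 215 counts over the BeWo libraries and 0 in JAR and JEG-3.

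**Figure D3:**
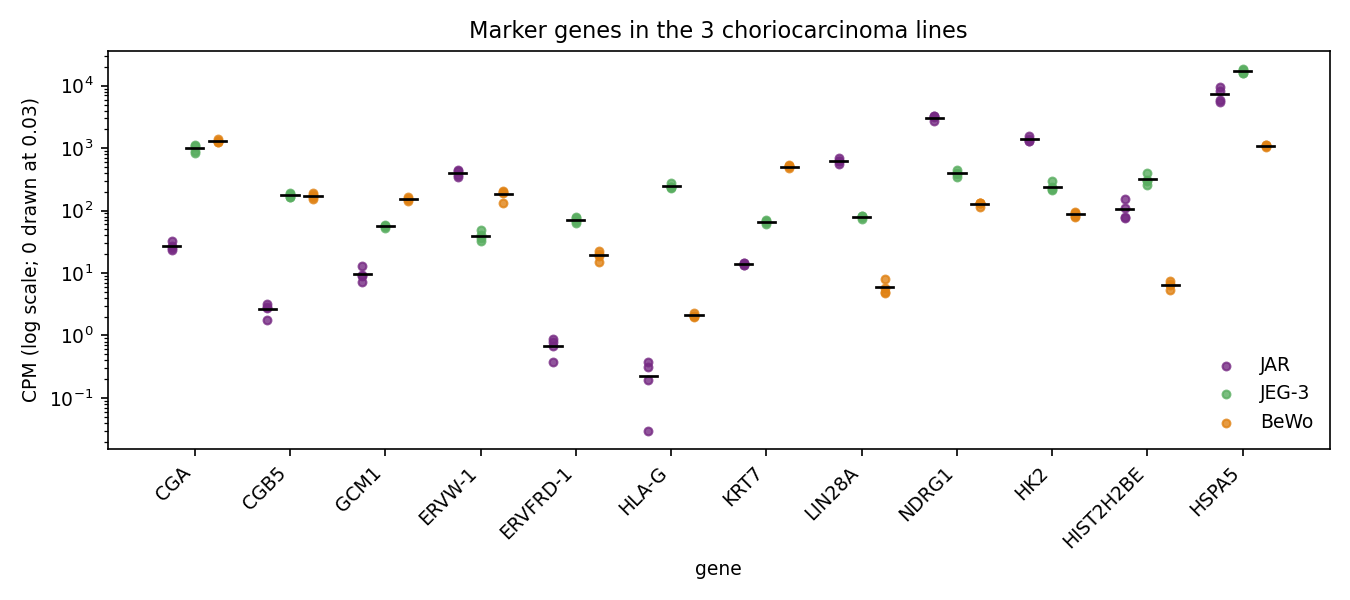
CPM of 12 genes in the 4 libraries of each line on a log scale, 1 point per library, with the mean of the 4 as a black bar and a value of 0 drawn at 0.03. HLA-G was at 247 CPM in JEG-3 against 0.221 in JAR and 2.09 in BeWo, and LIN28A at 625 in JAR against 78.6 in JEG-3 and 5.88 in BeWo.

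BeWo and JEG-3 differed far more in HLA-G than in CGA. CGA was higher in BeWo by 0.39 (SE 0.11), with an adjusted p of 0.0129 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CSH2 and GH2, placental lactogen and placental growth hormone genes that share reads with near-identical copies, rose by 7.35 (SE 0.28) and 6.28 (SE 0.22). CSH1, with 2 counts in JEG-3, had a ratio of 981 (counting interval 271 to 8108). HLA-G fell by 6.87 on the log2 scale (SE 0.22) and ERVFRD-1 by 1.90 (SE 0.16), and ERVW-1, GCM1, KRT7 and ASCL2 rose by 2.19, 1.43, 2.94 and 6.31. HSPA5 fell from 17111 ± 1275 to 1095 ± 30.4 CPM, the histone gene HIST2H2BE from 316 ± 56.7 to 6.42 ± 0.812, and LIN28A by 3.76 on the log2 scale (SE 0.12). TFAP2C and CDKN1A fell by 1.11 and 1.31, and GATA3 and MKI67 did not pass, at -0.11 (SE 0.11) and -0.57 (SE 0.48). TPTE, RASL10B, PLAC9 and ADRA2C had no count in JEG-3 and were at least 359-, 229.5-, 189.7- and 184-fold higher in BeWo. NLRP9 had 1 count there and a ratio of 1741 (counting interval 312 to 68805), and AKR1B10 and AGXT, an aldo-keto reductase and a peroxisomal aminotransferase, rose by 9.86 (SE 0.37) and 9.77 (SE 0.31). DNAL4 and ABHD3 had no count in BeWo and were at least 345- and 334-fold lower, and LDOC1 and MAGEH1 had 2 and 1 counts against 6746 and 3737. TMSB4X (chromosome X, 12975108 to 12977227), with 2 counts against 14935, FABP5 and its copy FABP5P7, at least 622- and 1102-fold lower, and the readthrough genes C15orf38-AP3S2 and INO80B-WBP1, at least 1561-fold lower and 227-fold higher, share sequence with copies or overlap other genes and are uncertain. INO80B-WBP1 stood at 0, 1.44, 18.3 and 20.6 CPM in the 4 BeWo libraries. In total 7854 of 11540 genes differed, 3886 higher and 3968 lower in BeWo, and 3274 of them by at least 2-fold (1764 higher, 1510 lower). With limma on log2(FPKM + 1), in which the median of all genes was 0.11, the split was 4645 higher and 3146 lower.

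By list, 11 of 12 histone genes were lower in BeWo than in JEG-3, with a median of -4.50, 19 of 22 hypoxia and glycolysis genes, with -1.56, and 15 of 20 stress response genes, with -1.43. Also lower were 18 of 22 p53 targets, with -0.76, 15 of 23 cholesterol synthesis genes, with -0.59, and 60 of 79 ribosomal protein genes, with -0.59. Camera gave them Benjamini-Hochberg adjusted p values of 3.5e-17, 2.0e-10, 6.2e-06, 5.8e-04, 0.00491 and 1.5e-05 at the preset correlation, and adjusted p = 0.0735, 0.146, 0.146, 0.146, 0.146 and 0.661 with an estimated correlation. Interferon-stimulated genes had a median of -1.74 with 14 of 18 lower and 1 higher, immediate early genes -1.26 with 9 of 15 lower and 1 higher, and pluripotency genes -0.33 with 7 of 11 lower and 2 higher. Camera gave these 3 lists adjusted p values of 0.0146, 0.00371 and 0.0336, and adjusted p = 0.661, 0.344 and 0.146 with an estimated correlation. On the higher side, extravillous genes had a median of 1.60 with 10 of 12 higher and 2 lower, and syncytium genes 1.27 with 10 of 17 higher and 4 lower. Hormone genes had 1.05 with 9 of 12 higher and 1 lower, and Wnt targets 1.01 with 4 of 7 higher and 2 lower, AXIN2 by 1.36 (SE 0.06). Their adjusted p in camera was 3.2e-04, 0.0146, 1.2e-05 and 0.0226, and adjusted p = 0.215, 0.146, 0.146 and 0.146 with an estimated correlation. Adjusted over the list alone, the counts were the same in these 13 lists. Of the 25 lists, 19 passed fry between JEG-3 and JAR, 18 between BeWo and JAR and 20 between BeWo and JEG-3, which tests the direction of a list on its own and not against other genes. No list passed fry with either inhibitor, in their difference or between the control sets, where the interferon list had an adjusted p in fry of 0.0502 with the miR-518a-3p inhibitor and 0.108 between the control sets.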

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

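In this part the comparison of each inhibitor with the other control set, the count of blood cell genes in JAR and JEG-3 alone and the test of the other inhibitor were chosen after seeing the data. Interferon-stimulated genes were lower with the miR-518a-3p inhibitor than in its own controls in all 3 lines (list median -1.92 on the log2 scale, and -2.88 in JAR, -1.72 in JEG-3 and -1.37 in BeWo; Benjamini-Hochberg adjusted p 3.2e-72 in camera, adjusted p = 0.0691 with an estimated correlation). The tables argue against blood immune cells as the source in JAR and JEG-3, where PTPRC, CD3E, CD14, LYZ and TYROBP together had at most 7 counts in the control libraries of that set, while in BeWo that control had 44 counts, between the bounds set in advance, against 46, 26 and 37 in the other 3 libraries, so these genes did not follow the interferon genes there, though 1 library a group leaves it open. A raised interferon response in those control libraries may account for most of the difference in JAR and BeWo and for less of it in JEG-3, since against the other control set the median was -0.37 (-0.09 in JAR, -0.80 in JEG-3 and -0.04 in BeWo). Against an effect of the miR-518a-3p sequence alone, the other inhibitor gave -0.97 in JEG-3, below the bound set against that explanation but from 1 pair of libraries, and its libraries against the controls of the miR-518a-3p set gave -2.15 (-2.64 in JAR, -1.75 in JEG-3 and -1.28 in BeWo), but this crosses the sets, so the explanation stays open, and what raised the response in the controls (reagent, transfection or handling) was not tested.

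Values of 1 library far from the other 3 of its line were found with Dixon's test, in 59 of 343 tests (17.2%), where chance gives about 1 in 20 groups, and many of the genes tested were named because they differed between libraries or belong to the interferon response.

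In JAR the values stand in CPM unless another unit is given, with the range of the other 3 libraries in brackets. The control of the miR-371a-5p set stood apart in CLDND1 167 (78.8 to 88.8). The miR-371a-5p inhibitor stood apart in TMSB4X 4.50 (0 to 0.247). The control of the miR-518a-3p set stood apart in the interferon list (mean log2 CPM) 4.94 (1.90 to 2.10), CCL5 10.1 (1.17 to 1.42), DDX60 27.1 (1.36 to 2.10), IFI6 1266 (367 to 412), IFIH1 10.5 (0.123 to 0.681), IFIT1 43.4 (0.0972 to 1.18), IFIT3 5.96 (0.0972 to 0.247) and IFITM1 98.8 (4.18 to 6.93). In the same library of JAR apart were IFITM3 68.9 (3.21 to 4.95), IFNL1 10.5 (0 to 0.433), IFNL3 18.8 (0.292 to 0.619), INO80B-WBP1 20.5 (0), ISG15 426 (34.7 to 40.2), PFKFB3 228 (70.0 to 85.1), PLSCR1 42.0 (11.9 to 15.8) and SLC7A5P2 6.66 (1.36 to 2.17). In the same library of JAR apart were CASP7 2.54 (0.370 to 0.681) and RRM2 620.1 (402 to 429).

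In JEG-3 the values stand in CPM unless another unit is given, with the range of the other 3 libraries in brackets. The control of the miR-371a-5p set stood apart in RAB11A 302 (122.8 to 134) and DGCR8 10.7 (13.7 to 14). The miR-371a-5p inhibitor stood apart in ASCL2 1.63 (2.32 to 2.39) and TSN 58.1 (6.19 to 8.12). The control of the miR-518a-3p set stood apart in the percentage of mitochondrial counts 5.49 (6.54 to 6.64), CCL5 106 (3.65 to 7.48), IFIT3 67.8 (14.4 to 22.0), IFNL1 21.9 (1.57 to 2.94), IFNL3 16.2 (0.674 to 2.09), PFKFB3 43.2 (12 to 14.2) and SERPING1 81.0 (43.3 to 48.3). The miR-518a-3p inhibitor stood apart in HMGCS1 565 (99.9 to 147), CDH1 459 (295 to 319) and HMOX1 13.4 (10.5 to 10.9).

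In BeWo the values stand in CPM unless another unit is given, with the range of the other 3 libraries in brackets. The control of the miR-371a-5p set stood apart in CLEC4GP1 7.67 (9.85 to 10.1) and SENP3-EIF4A1 8.41 (0 to 0.319). The miR-371a-5p inhibitor stood apart in CCDC69 8.77 (43.9 to 50.2), MKI67 26.1 (85.9 to 89.6), TRIM52 10.3 (1.11 to 2.05) and VPS26A 37.7 (15.1 to 17.9). The control of the miR-518a-3p set stood apart in the total count (in units of 1e6) 16.9 (19.7 to 19.9), the interferon list (mean log2 CPM) 5.16 (3.50 to 3.63), CCL5 5.56 (0.139 to 0.279), DDX60 18.2 (3.74 to 4.32), DHCR24 185 (139 to 143), ERVW-1 133 (193 to 205), IFI6 826 (243 to 277) and IFIH1 9.53 (1.66 to 2.55). In the same library of BeWo apart were IFIT1 6.62 (0.370 to 0.650), IFIT3 6.30 (0.274 to 0.604), IFITM1 130.1 (48.7 to 59.4), ISG15 64.7 (30.4 to 33.1), NDRG1 112 (131 to 134), NLRP9 18.1 (26.8 to 27.9) and PCDHB2 2.54 (15.1 to 17.6). The miR-518a-3p inhibitor stood apart in ADRA2C 7.62 (8.05 to 8.13), AXIN2 115 (120.3 to 121), CLDND1 75.3 (10.0 to 16.3) and PFKFB3 3.79 (10.6 to 11.6).

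For the response to the miR-518a-3p inhibitor minus that to the miR-371a-5p inhibitor, 5 lists passed camera at the preset correlation. With an estimated correlation 0 lists passed, and 0 passed fry. For the interferon list the median difference was -1.44 on the log2 scale (Benjamini-Hochberg adjusted p 5.5e-29 in camera, adjusted p = 0.347 with an estimated correlation). For hypoxia and glycolysis the median difference was -0.13 on the log2 scale (Benjamini-Hochberg adjusted p 1.1e-04 in camera, adjusted p = 0.833 with an estimated correlation). For nuclear genes of oxidative phosphorylation the median difference was 0.16 on the log2 scale (Benjamini-Hochberg adjusted p 5.8e-05 in camera, adjusted p = 0.824 with an estimated correlation). For ribosomal proteins the median difference was 0.14 on the log2 scale (Benjamini-Hochberg adjusted p 2.0e-06 in camera, adjusted p = 0.833 with an estimated correlation). For mitochondrial transcripts the median difference was 0.32 on the log2 scale (Benjamini-Hochberg adjusted p 2.8e-07 in camera, adjusted p = 0.824 with an estimated correlation).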

How the results depend on the processing

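In this part the fits against the other control set, against both control sets and without the controls of the miR-518a-3p set were chosen after seeing the data. Counts here are genes from edgeR's quasi-likelihood test unless another tool is named, given for the miR-371a-5p inhibitor (0 genes in the report), the miR-518a-3p inhibitor (1), the control sets (1) and the difference between inhibitors (0), and lists are those that passed camera of 25. Where a count changed, the cause was not tested unless the sentence gives it.

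Without a filter on low values, which tests more genes, these counts were 1, 16, 3 and 1, with 15032 genes between BeWo and JAR and 12110 between BeWo and JEG-3, and lists numbered 2 and 5 for the inhibitors, 3 for the control sets and 10 between JEG-3 and JAR. At a mean FPKM of at least 5, which tests fewer genes, they were 1 for the miR-371a-5p inhibitor, 4272 between BeWo and JAR, 3681 between BeWo and JEG-3 and 4138 between JEG-3 and JAR, with 3 lists there. DESeq2 called 4, 34, 26 and 3. limma on log2(FPKM + 1) called 1 and 0 genes for the inhibitors and 2 for the control sets, limma on log2(FPKM + 0.1) 1, 0 and 0, and limma on quantile-normalized and on median-ratio scaled FPKM 0 for the miR-518a-3p inhibitor. With a pseudocount of 0.1 limma called 5811 genes higher and 3491 lower between BeWo and JAR, 4555 and 3148 between BeWo and JEG-3, and 5062 and 3621 between JEG-3 and JAR. CDKN1A reversed between BeWo and JAR, to 0.10 and 0.10 in limma with pseudocounts of 1 and 0.1 and 0.0932 after quantile normalization, called in none of these, and the cause was not tested.

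Without the replicate block the miR-518a-3p inhibitor changed 0 genes and 2 lists, and the paired fit with line as the block called 1 gene for the miR-371a-5p inhibitor and lost PFKFB3 while it called CCL5 for the miR-518a-3p inhibitor. The block changed no other count of calls by over 1.5 times. With only the 6 libraries of its set the miR-518a-3p inhibitor changed 0 genes. Leaving out 1 line gave 0 to 1 genes for each inhibitor, with PFKFB3 in none, 1 to 5 for the control sets and 0 for the difference, and 2 to 3, 3 to 9, 6 to 10 and 3 to 7 lists in that order, with fewer libraries in each fit. Against the other control set 1 gene and 8 lists were called for the miR-371a-5p inhibitor and 0 genes and 4 lists for the miR-518a-3p inhibitor, and against both control sets 0 genes and 5 lists for the latter. Of those 4 lists, interferon and mitochondrially encoded genes kept their direction. Hypoxia and immediate early genes were higher there and lower against their own controls (Benjamini-Hochberg adjusted p 0.00247 and 0.0263 in camera, adjusted p = 0.664 with an estimated correlation for each). With an estimated correlation 1 list passed between BeWo and JAR and 1 between the control sets, and 0 in each of the other 5 comparisons, while against the other control set the interferon list alone passed for the miR-371a-5p inhibitor (adjusted p = 0.0290 with an estimated correlation in camera).

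For the interferon median, leaving out 1 line gave 1.06 to 2.21 for the control sets, -1.90 to -0.96 for the difference, -0.70 to -0.0029 for the miR-371a-5p inhibitor and -2.38 to -1.64 for the miR-518a-3p inhibitor, the values nearest 0 without JAR, or without JEG-3 for the miR-371a-5p inhibitor. It moved by over 1.5 times to 1.12 for the control sets in limma on log2(FPKM + 1), to 1.10, -0.24 and -1.27 for the control sets and the inhibitors after quantile normalization, and to -0.67 for the miR-371a-5p inhibitor without the block. Against the other control set it was -2.15 for the miR-371a-5p inhibitor and -0.37 for the miR-518a-3p inhibitor, and against both -1.495 for the former.

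Genes with a change the same way in all 3 lines, a count without a test, numbered 17, 4 and 23 at 1.5-fold for the control sets and the miR-371a-5p and miR-518a-3p inhibitors, and 11, 4 and 19 at 2-fold with a pseudocount of 0.1. With 8mer sites alone the miR-518a-3p difference was weaker, 0.0089. For named genes, 2283 fits between BeWo and JAR were the same (14 stronger, 18 weaker, 3 reversed). Between BeWo and JEG-3 2299 were the same (6 moved, 2 stronger, 11 weaker), and between JEG-3 and JAR 2232 (7 stronger, 18 weaker). Stronger and weaker fits gained or lost a call with the sign kept, and reversed ones changed sign with a call in either fit. Moved ones changed sign by more than the SE without a call in either fit. The same fits kept sign and side of the threshold, or changed sign within the SE without a call. For the inhibitors 1933 and 1873 fits of named genes were the same, 50 and 51 moved, 3 and 18 were stronger and 0 and 12 weaker.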

Other observations

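In this part the intervals of the odds ratios were added after those ratios were seen, the 7-mers of the same base composition and the comparison with the other control set were added after the first results were seen, with the predictions for both written before they were run, and the other tests were set before any result. Single genes of microRNA silencing differed between the lines. AGO2, the Argonaute that cleaves paired transcripts, stood at 120.1 ± 14.9, 23.7 ± 2.87 and 37.2 ± 2.14 CPM in JAR, JEG-3 and BeWo (SD, n = 4), and TNRC6A (GW182), which links Argonaute to the deadenylases, at 77.5 ± 9.40, 9.18 ± 1.31 and 8.47 ± 1.27. Both were called lower in JEG-3 and in BeWo than in JAR, AGO2 by -2.34 (SE 0.09) and -1.68 (SE 0.09) on the log2 scale and TNRC6A by -3.08 (SE 0.15) and -3.20 (SE 0.15). DGCR8, the partner of Drosha, was higher in BeWo than in JEG-3 by 1.62 (SE 0.16) and XPO5, which exports microRNA precursors, by 0.87 (SE 0.11), and ZCCHC6, a uridylyl transferase of microRNA precursors, was higher in JEG-3 than in JAR by 1.46 (SE 0.13). Of 15 genes of this list, 2 were called higher and 9 lower between JEG-3 and JAR, 5 and 7 between BeWo and JAR, and 5 and 3 between BeWo and JEG-3, with the same counts adjusted over the list alone. The list passed camera in no comparison, and the smallest Benjamini-Hochberg adjusted p in camera was 0.0697 (adjusted p = 0.615 with an estimated correlation), between JEG-3 and JAR. No member was called with either inhibitor by edgeR's quasi-likelihood test.

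Further lists passed camera in no comparison, while single members differed widely between the lines. CCNE1 (cyclin E1), which drives entry into S phase, stood at 42.2 ± 3.95, 206 ± 3.65 and 452 ± 31.8 CPM in JAR, JEG-3 and BeWo, the replicative helicase subunit MCM5 at 48.4 ± 3.78, 197 ± 6.70 and 151 ± 3.12, and RRM2, a subunit of ribonucleotide reductase, at 465 ± 104, 177 ± 11.7 and 74.6 ± 3.13. Each pair of lines differed in these 3 genes, and of 31 cell cycle genes 19 were called higher and 6 lower between JEG-3 and JAR, with an adjusted p in camera for that pair of lines, the smallest of the 3 pairs, of 0.0974 (adjusted p = 0.787 with an estimated correlation). HMOX1, heme oxygenase 1, stood at 86.8 ± 23.3, 11.4 ± 1.37 and 285 ± 5.85 CPM, and NQO1, a quinone reductase of the same oxidative stress list, at 7.92 ± 1.83, 49.8 ± 3.09 and 13.6 ± 2.22. Among apoptosis genes the survival factor MCL1 stood at 960.3 ± 51.2, 517 ± 38.5 and 259 ± 4.98 CPM and the executioner CASP7 at 1.05 ± 0.999, 13 ± 3.10 and 16.6 ± 0.393. Of imprinted genes, PHLDA2, a growth restraint of the placenta, stood at 0.831 ± 0.420, 3.60 ± 0.649 and 63.2 ± 7.20 CPM, and IGF2, the fetal growth factor, at 3.02 ± 0.708 in JAR and 0.660 ± 0.356 in BeWo, with 50.6, 369, 387 and 72.1 in the 4 JEG-3 libraries. PLAU (urokinase), of the invasion list, had no count in JAR and was at least 93.8-fold higher in JEG-3 and 215-fold higher in BeWo, while the epithelial cadherin CDH1 stood at 342 ± 12.7, 347 ± 74.9 and 335 ± 23.3 CPM and was not called in any pair. ICAM1, an NF-kB target, was called lower in JEG-3 than in JAR, by -1.47 (SE 0.12) on the log2 scale. The smallest adjusted p in camera over the 3 pairs of lines was 0.438 for oxidative stress, 0.501 for apoptosis, 0.700 for imprinted genes, 0.438 for invasion genes and 0.883 for NF-kB targets. The counts called between BeWo and JAR were 6 higher and 5 lower of 16, 7 higher and 6 lower of 15, 4 higher and 4 lower of 9, 7 higher and 4 lower of 13 and 1 higher and 2 lower of 6 in that order.

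Single genes jumped between libraries of one line, as SNX22 did in JEG-3, at 0.613, 58.9, 0.588 and 54.5 CPM in control and inhibitor of the miR-371a-5p set and control and inhibitor of the miR-518a-3p set. CCNT1 in JEG-3 (51.5, 51.1, 51.0 and 0.332 CPM) and IL6ST in BeWo (68.7, 71.8, 1.06 and 79.6 CPM) were chosen after their values were seen, and 408 of 9684 genes with a mean of at least 200 counts in a line (4.21%), outside the interferon list, differed at least 3-fold between the libraries of that line. The tables argue against reads shared with named pseudogene copies (odds ratio 0.797, 95% interval 0.575 to 1.10, Fisher's exact test p 0.116). Copies were found by gene name alone, so shared reads themselves were not measured. Here and for overlapping genes, the odds ratio and its interval are stratified by count, while Fisher's p comes from the unstratified shares. Reads of overlapping genes counted for one gene or the other stay open, since 32.1% of jumping and 30.5% of other genes overlapped an expressed gene (odds ratio 1.09, 95% interval 0.878 to 1.34, Fisher's exact test p 0.476) while jumping genes moved opposite to an overlapping gene in 58.3% of 204 pairs, against 46.6% for random partners. Low counts stay open too, since at a mean of at least 2000 counts the share was 2.05%, 0.486 of that at the lower minimum, between the bounds set for either verdict, and no biological explanation was tested.

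Genes with a miR-518a-3p seed site were slightly higher with its inhibitor than genes without one. Their median log2 fold change was higher by 0.026, a difference above each of the 100 other 7-mers. Shuffling the fold changes over genes, which treats genes as independent, gave this difference an SD of 0.0107. Base composition of the site is argued against, since 100% of 86 7-mers of the same composition lay below the difference. A raised interferon response in the controls of that set is argued against as the whole source, since against the other control set the difference was 0.021, above 99% of the other 7-mers. By line it was less even there, at -0.056 in JAR (above 56%), 0.050 in JEG-3 (above 68%) and 0.061 in BeWo (above 98%). What stays open is chance, since 8 camera tests of site genes gave none that passed (Benjamini-Hochberg adjusted p 0.524 in camera) and the 38 genes with an 8mer site had a difference of 0.0089, above 73.7% of other 8-mers. With 7mer-A1 sites added, the difference was 0.019 with the miR-518a-3p inhibitor, above all 100 other 7-mers. With the miR-371a-5p inhibitor it was then -0.0005, below all 100, so an extreme also arose with the other inhibitor. A weak release of microRNA targets may therefore be one hypothesis among others, and the size of 0.026 lies far under the 2-fold scale of the gene counts.

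Other splits of the same libraries were run for each count of genes from edgeR's quasi-likelihood test. For the miR-371a-5p inhibitor, the miR-518a-3p inhibitor and the control sets the 6 libraries make 10 splits, too few for a share under 0.05, with real counts of 0, 1 and 1, highest other counts of 21, 33 and 1, and 10, 7 and 4 splits with at least the real count. The splits with 21 and 33 genes part only 1 pair of libraries, and the pair blocks absorb the unparted pairs. Their contrast therefore rests on 1 library against 1 library of the same line. Among the 4 splits that part all 3 lines the highest other counts were 0, 0 and 1. For the difference between the inhibitors the real count was 0 and the highest other 1, and since all 32 splits must reach a count of 0, as the 10 for the miR-371a-5p inhibitor must, these splits decide nothing about chance. Between the lines the real counts were 8678, 9193 and 7854, and the highest other counts 1, 0 and 1 in 35 splits each. Only 1 split, the real one, reached the count, a share of 2.86%, the smallest that 35 splits can give. Every other split puts libraries of both lines on each side, which by itself leaves few genes to call. Alone, these splits therefore do not exclude chance.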
